A study of Drosophila melanogaster with 36 samples.

How the data were processed

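Messenger RNA levels of whole adult female Drosophila melanogaster were measured on a 1-colour oligonucleotide array with biotin-labelled total RNA. Per the labels, the 36 arrays came from 2 lines, a nonselected line and a line selected for heat resistance. Each line was sampled untreated and at 8 times after 1 h at 36 °C, namely 0.25, 1, 2, 4, 8, 16, 32 and 64 h, with 2 biological replicates per line and time, which makes 18 groups of 2. The labels do not say how many populations were selected, how many flies were pooled, or at what time of day flies were collected.

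The deposited values are intensities on a linear scale, made by the authors with GCRMA, per the submitters' processing notes, which give no version. GCRMA subtracts a background predicted from probe sequence, normalizes between arrays and summarises the probes of each probe set. The scale was read from the values, which ran from 1.15 to 46856 and were all positive, and log2 was taken without a pseudocount. Of 14010 probe sets, 44 array controls were left out of the tests. No 2 arrays held identical values, and 0 value columns were left unused. Read depth does not apply to arrays, and the number of arrays limits the precision. The median intensity per array ran from 43.5 to 52.0.

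Probe sets were named through GEO's platform annotation. Of 13966 probe sets that are not controls, 12443 had 1 gene symbol, 327 had several and 1196 had none. Symbols were updated through the Entrez identifier with the RefSeq gene table of the Release 6 plus ISO1 MT assembly, which matched 12394. No genome build is named in the sources used here, so no coordinates are given. Probe sets with several genes were named as no gene. Several abundant heat shock genes, most ribosomal protein genes and other families lack a probe set with 1 symbol in this annotation, so their lists are only partly covered.

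A probe set was tested when the mean of its 4 highest arrays was at least 5 on the log2 scale, an intensity of 32. This left 8199 probe sets, 7312 of them with 1 symbol, for 6884 genes. One linear model with a coefficient for each of the 18 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, 18 residual degrees of freedom). The heat response at each time was the mean of both lines at that time minus the mean of both untreated groups, 4 arrays against 4. Per the labels, no untreated flies were sampled alongside the later times. At late times this contrast therefore holds heat, age and time of day together, and time of day can differ at earlier times too. Further contrasts were a moderated F-test over the 8 times, the line difference (selected minus nonselected) averaged over the 9 times and in untreated flies, and the line by time interaction. All p-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. The replicate numbers did not enter the fit. Where adjusted p-values are printed, they come from limma. The values carry no detection calls. Where an array on the lower side of a comparison lay under an intensity of 32, such arrays were set to 32 and the fold is given as at least the ratio, or the levels or the fitted log2 change are given.

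18 gene lists were written before the data were examined: heat shock proteins, constitutive chaperones, proteasome, antimicrobial and immune recognition, Turandot stress genes, detoxification, antioxidant defence, glycolysis, digestive serine proteases, yolk and eggshell, ribosomal proteins, flight and body muscle, photoreceptor, fat body and haemolymph proteins, circadian clock, male reproductive, cell cycle and replication, and odorant-binding and chemosensory proteins. A germline list was added later, before its own values were examined. Each gene was represented by its probe set of highest mean. Members past the threshold were counted, adjusted over all probe sets and adjusted over the list alone, and each list was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over lists and contrasts. Of the 64 list calls of camera, 4 held with an estimated correlation, those of the heat shock proteins at 0.25, 1, 2 and 4 h.

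The genes named in the text follow a rule set before the data were examined. For each time it takes the 5 highest and 5 lowest changes past the threshold among probe sets with 1 symbol and no overlap between the 4 arrays and the 4 untreated arrays. For the line difference it takes the 10 highest and 10 lowest with the same sign at all 9 times, for the untreated line difference 5 and 5, and for the interaction F-test the 10 smallest p. Any member of the gene lists may be named, with the largest changes as examples, and every measured heat shock protein gene is named. The rule took 74 genes, of which 28 have a CG number only and are mostly left unnamed, as are some genes that recur. Genes behind counts of 5 or fewer, a probe set without a symbol, 2 probe sets of several heat shock genes, LysS, and genes of single arrays were chosen after their values were seen, as the text says.

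The fit was tested on simulated data with the real means and residual SDs of 8199 probe sets, 200 of them changed. For the heat response at 1 h, 36% of 1.5-fold, 84% of 2-fold, 98% of 4-fold and 100% of 8-fold changes were recovered, with 4 false among 163 calls. For the line difference over all times, 94% of 1.5-fold changes were recovered, with 8 false among 204 calls. The simulated arrays were independent, whereas real arrays of a line and replicate number were correlated (consensus correlation 0.392). The recovery and false calls of the line difference therefore do not carry over to the real data. For the interaction at 1 h, 10% of 1.5-fold, 30% of 2-fold, 74% of 4-fold and 94% of 8-fold changes were recovered, with 2 false among 106 calls.

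Alternatives set before the data were examined were a replicate block, the same within line, a random block of line and replicate number, line means of 2 against 2, no filter and a stricter filter (7 on the log2 scale), trend and robust moderation, added quantile normalization, median centring, a pseudocount of 16, fits of only the arrays compared, a minimum log2 change of 1, an adjusted p threshold of 0.01, the 64 h arrays as reference, each array left out in turn, and other list tests (estimated correlation, averaged probe sets, fry). Leaving out the tested probe sets more than 2 log2 units above all other arrays in selected 32 h replicate 2 was added after the data were seen. RNA quality was described by the log2 ratio of the 3' to the 5' probe sets of 3 fly control transcripts (actin, GAPDH and eIF-4a), averaged per array. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.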

Results

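The data comprised 36 arrays of whole adult female flies of a nonselected line and a line selected for heat resistance. Flies were untreated or sampled 0.25, 1, 2, 4, 8, 16, 32 or 64 h after 1 h at 36 °C, with 2 biological replicates for each of the 18 combinations of line and time. Values are background-corrected intensities, compared on the log2 scale. The median residual SD of the 8199 tested probe sets was 0.24 log2 units. Between 7414 and 7843 probe sets per array reached an intensity of 32. The 3' to 5' signal of the control transcripts separated the replicate numbers. Its log2 ratio was 2.28 ± 0.20 (SD, n = 18) in replicate 1 arrays and 1.55 ± 0.14 (SD, n = 18) in replicate 2 arrays, with no overlap (lowest 1.83 against highest 1.79, 2-sided permutation p = 1e-05, the smallest that the permutations can give). Each replicate number held every line and time. The mean ratio was 1.93 in the selected and 1.89 in the nonselected line (permutation p = 0.746), and its means over the 9 times lay between 1.78 and 2.05 (permutation p = 0.993).

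The first comparison asked which transcripts differed from untreated flies at each time after heat. Without untreated flies sampled alongside the later times, late differences cannot be tied to heat rather than to age or time of day. Heat shock chaperones led the increases from 0.25 to 2 h, and eggshell transcripts were among those that fell at 8, 16 and 64 h. Of 8199 probe sets, 1086 changed over the series (moderated F-test). Their largest change lay at 0.25 to 2 h in 358 (33.0%), at 4 or 8 h in 144 (13.3%) and at 16 to 64 h in 584 (53.8%). Single times gave 62 probe sets at 0.25 h (42 higher, 20 lower), 104 at 1 h (73 and 31), 96 at 2 h (64 and 32) and 29 at 4 h (18 and 11). Later times gave 87 at 8 h (58 and 29), 196 at 16 h (121 and 75), 90 at 32 h (56 and 34) and 293 at 64 h (183 and 110). These counts depend on leaving the replicate number out of the fit. With a replicate block they were higher at every time, for example 121 at 0.25 h and 615 at 64 h, with 2064 over the series. Fitted separately for each replicate number, log2 changes across probe sets correlated between replicate 1 and replicate 2 arrays, which share no arrays, with Pearson's r from 0.414 at 2 h to 0.808 at 64 h. Probe sets are not independent replicates. Between 8 probe sets at 4 h and 96 at 64 h passed in both replicate numbers with the same sign.

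**Figure D1:**
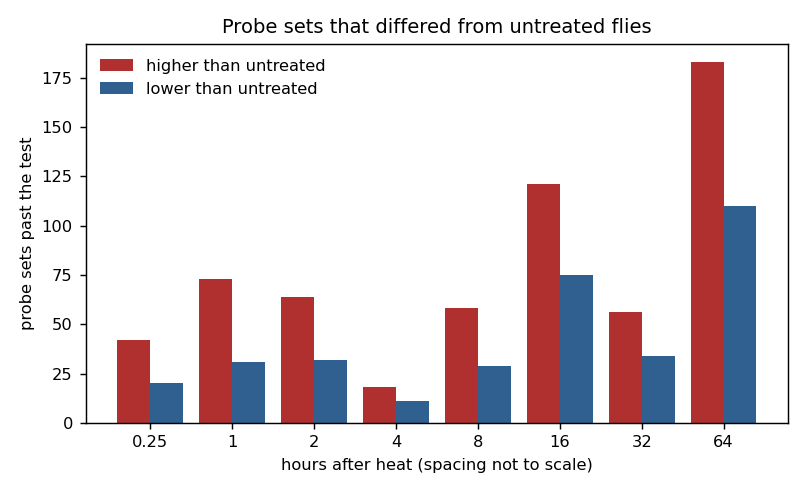
Bars give the number of probe sets (y axis) past the limma test at each time after heat (x axis, hours), higher (red) or lower (blue) than in untreated flies, 4 arrays against 4. The counts fell to 29 at 4 h and were highest at 64 h, with 183 higher and 110 lower.

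Heat shock transcripts rose within 0.25 h of the end of heat. Hsp68, an inducible chaperone of the Hsp70 family, went from 8.86 ± 0.53 to 14.62 ± 0.22 log2 units (SD, n = 4), 53.9-fold (log2 change 5.75, SE 0.26, adjusted p = 1.33e-12). The transcript of stv (starvin), a BAG-domain co-chaperone, rose 20.8-fold (log2 change 4.38, SE 0.40, adjusted p = 3.8e-07). DnaJ-1, an Hsp40 co-chaperone, rose 3.90-fold, and the small heat shock protein genes Hsp27 and Hsp26 rose 3.55-fold and 3.01-fold. Hsf, the heat shock transcription factor gene, stood at 1.36-fold (adjusted p = 0.686) and Stip1, a co-chaperone of Hsp70 and Hsp90, at 1.27-fold (adjusted p = 0.412). Thus 5 of the 7 measured members of the heat shock protein list rose at 0.25 h, and the same number at 1 h and at 2 h (7, 7 and 6 adjusted over the list alone). The camera test of this list gave adjusted p = 6.12e-33 at 0.25 h, and adjusted p = 5.63e-07 with an estimated correlation.

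Among the 7 measured members of the heat shock protein list, Hsp68 and stv passed the test as higher for the longest time. Hsp68 remained 15.2-fold above untreated flies at 4 h, 9.77-fold at 8 h and 2.59-fold at 16 h (adjusted p = 0.00357), and stood at 1.61-fold at 32 h (adjusted p = 0.242). The stv transcript was 5.87-fold higher at 8 h (adjusted p = 0.00173) and 2.13-fold at 16 h (adjusted p = 0.212). DnaJ-1, Hsp27 and Hsp26 passed the test at 0.25, 1 and 2 h and not at 4 h, where Hsp27 stood at 1.69-fold (adjusted p = 0.408). DnaJ-1 fell below the untreated level at 16 h (log2 change -0.74, SE 0.20, adjusted p = 0.0498) and at 64 h (-0.73, SE 0.20, adjusted p = 0.0397), and stood at -0.71 at 32 h (adjusted p = 0.0891). The list test at 8 h (adjusted p = 0.000142) was lost with an estimated correlation (adjusted p = 0.0581). Probe sets that the annotation does not tie to 1 gene were chosen after their values were seen. That of the near-identical copies Hsp70Ba, Hsp70Bb, Hsp70Bbb and Hsp70Bc rose by 3.73 log2 units at 0.25 h, and fell by 3.56 at 64 h (SE 0.30 each, adjusted p = 3.31e-08 and 4.38e-07). That annotated to both Hsp22 and CG4456 rose 32.3-fold at 0.25 h and was still 6.47-fold higher at 32 h (adjusted p = 0.000542). A probe set that carries no symbol here rose 91.8-fold at 0.25 h.

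**Figure D2:**
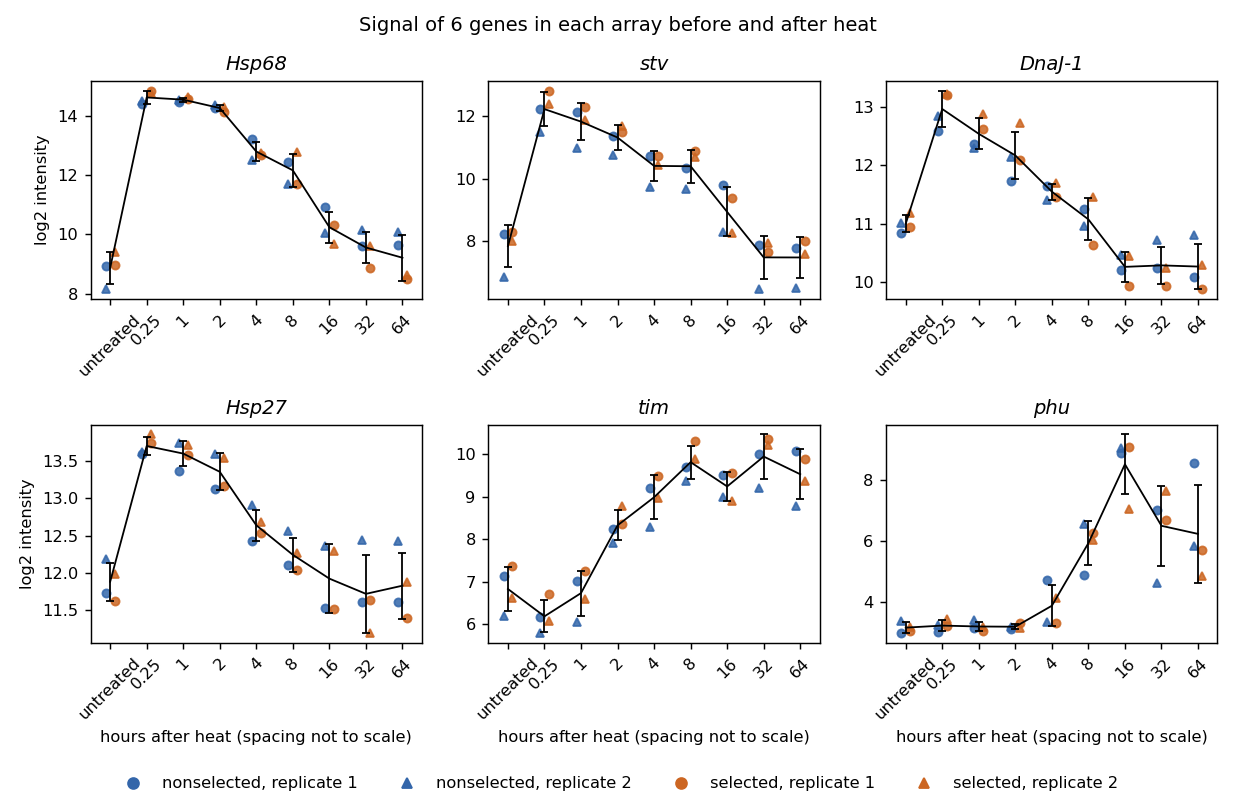
Log2 intensity (y axis) of 6 genes in each of the 36 arrays, untreated and by hours after heat (x axis, not to scale). Circles are replicate 1, triangles replicate 2, blue nonselected and orange selected, and the black line gives the mean with the SD of 4 arrays. Hsp68 rose from a mean of 8.86 to 14.62 at 0.25 h, and phu from 3.15 in untreated flies to 8.50 at 16 h.

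Glutathione S-transferase genes were among the other transcripts that rose in the first 2 h. At 1 h 4 of the 39 measured detoxification genes rose, all of this family. GstD2 was 3.74-fold, GstE1 2.95-fold, GstE7 2.27-fold and GstD10 at least 1.69-fold higher, where at least marks a change with arrays under an intensity of 32 on its lower side. At 2 h GstD2 (4.14-fold, adjusted p = 0.00892), GstE1, GstD10 and the cytochrome P450 gene Cyp6a23 (2.89-fold) rose. The P450 gene Cyp6g1 fell at 0.25 h and 1 h, by 0.81 log2 units at 1 h (adjusted p = 0.0075). Adjusted over the list alone, 7 members rose and 2 fell at 1 h. The camera test of the list gave adjusted p = 0.816 at 1 h. Of the 19 measured antioxidant genes, Keap1, a regulator of the oxidative stress response, rose 1.99-fold at 1 h, and Gclm, a subunit of the enzyme of glutathione synthesis, rose 1.52-fold at 1 h and 1.48-fold at 2 h. At 0.25 h AANATL3 fell at least 2.06-fold, 18w, a receptor of the Toll family, by 1.36 log2 units (SE 0.27), and Cyp18a1, which inactivates the moulting hormone, by 1.16 (SE 0.25). At 2 h kumpel fell by 1.30 log2 units. Among genes with a CG number only, CG12224 rose 5.37-fold at 1 h, CG2065 at least 4.19-fold at 1 h, and CG6785 from a low level of 3.50 to 5.94 ± 0.30 log2 units at 0.25 h (SD, n = 4).

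These early counts fell whichever array was left out. The lowest counts were 39 at 0.25 h, 47 at 1 h and 53 at 2 h, each without selected untreated replicate 1. Of the 10 genes that the rule took at each time, 5, 5 and 4 kept their call whichever array was left out, Hsp68 and stv among them each time. GstD2 lost its call at 2 h without selected untreated replicate 1, and kumpel at 2 h and AANATL3, 18w and Cyp18a1 at 0.25 h lost theirs when 1 of several arrays was left out.

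Clock genes and MtnA were among the transcripts that rose up to 8 h. The clock gene tim rose 2.83-fold at 2 h, 4.48-fold at 4 h and 7.95-fold at 8 h (log2 change 2.99, SE 0.32, adjusted p = 9.65e-06), and vri, which represses clock transcription, rose at least 2.11-fold at 1 h and at least 2.35-fold at 8 h. The transcript of cry, the blue light receptor of the clock, fell by 0.74 log2 units at 8 h. Thus 2 of the 8 measured clock genes rose and 1 fell at 8 h (3 and 1 adjusted over the list alone). All times were compared with the same untreated flies, and the labels give no time of day. Heat therefore cannot be told apart from time of day for these clock genes, also at 1 to 4 h. MtnA, a metallothionein, rose 5.86-fold at 8 h (SE 0.55 log2, adjusted p = 0.0193). Alp2, an alkaline phosphatase gene, rose at least 6.83-fold at 8 h, and phu rose to 5.91 ± 0.72 log2 units (SD, n = 4) from 3.15, close to the background of the arrays. The hexokinase gene Hex-C, the 1 glycolysis gene of 15 that passed at any time, was 1.67-fold lower at 1 h and 1.73-fold higher at 8 h.

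Digestive protease and eggshell transcripts were among those that fell at 4 and 8 h. Of 26 digestive serine protease genes, 2 fell at 4 h (8 adjusted over the list alone), Jon44E by 2.21 log2 units (SE 0.42, adjusted p = 0.0146) and Jon25Biii by 0.95. The camera test of this list at 4 h (adjusted p = 4.54e-21) was lost with an estimated correlation (adjusted p = 0.239). LysC, a lysozyme gene whose probe set belongs to a family of similar sequences and so may not be specific, was 4.29-fold lower at 4 h (adjusted p = 0.044). At 8 h 3 of the 22 yolk and eggshell genes fell (10 adjusted over the list alone). Fcp3C, a follicle cell gene, went from 9.52 ± 0.32 to 3.88 ± 1.18 log2 units (SD, n = 4, adjusted p = 0.0155). Vm32E, a vitelline membrane gene, fell by 4.55 (SE 1.11) and dec, another eggshell gene, by 4.36 (SE 0.96). Obp19c, of the odorant-binding family, fell from 9.62 to 4.62 ± 1.46 log2 units (SD, n = 4, adjusted p = 0.00447), the 1 of 12 measured members that did. Of the 10 genes taken at each time, 4 at 4 h and 5 at 8 h kept their call whichever array was left out. Those of Jon44E and LysC at 4 h and of phu, Fcp3C, Vm32E and dec at 8 h were lost when 1 of several arrays was left out, and the counts went down to 12 at 4 h without selected 4 h replicate 2 and to 36 at 8 h without selected 8 h replicate 1.

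At 16 h the transcripts of chorion proteins, which form the outer eggshell, were far below the untreated level. Cp19 fell from 13.42 ± 0.37 to 6.03 ± 1.64 log2 units (SD, n = 4), at least 158-fold (log2 change -7.40, SE 1.04, adjusted p = 0.000266). Cp18 was at least 80.9-fold, Cp38 at least 71.3-fold, Cp7Fc at least 59.1-fold and Cp16 at least 56.2-fold lower, with 2 or 3 of 4 arrays under an intensity of 32. In all, 11 of the 22 yolk and eggshell genes fell at 16 h and none rose (11 adjusted over the list alone). The yolk protein genes Yp1, Yp2 and Yp3, which belong to the same list, did not pass at 16 h, and the median change of these 3 was -0.12. The camera test of the list (adjusted p = 6.62e-16) was lost with an estimated correlation (adjusted p = 0.305). The 29 measured genes of a germline list, transcripts of nurse cells and oocytes, had a median log2 change of -0.10 ± 0.17 (SD over genes) at 16 h, and none passed.

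**Figure D3:**
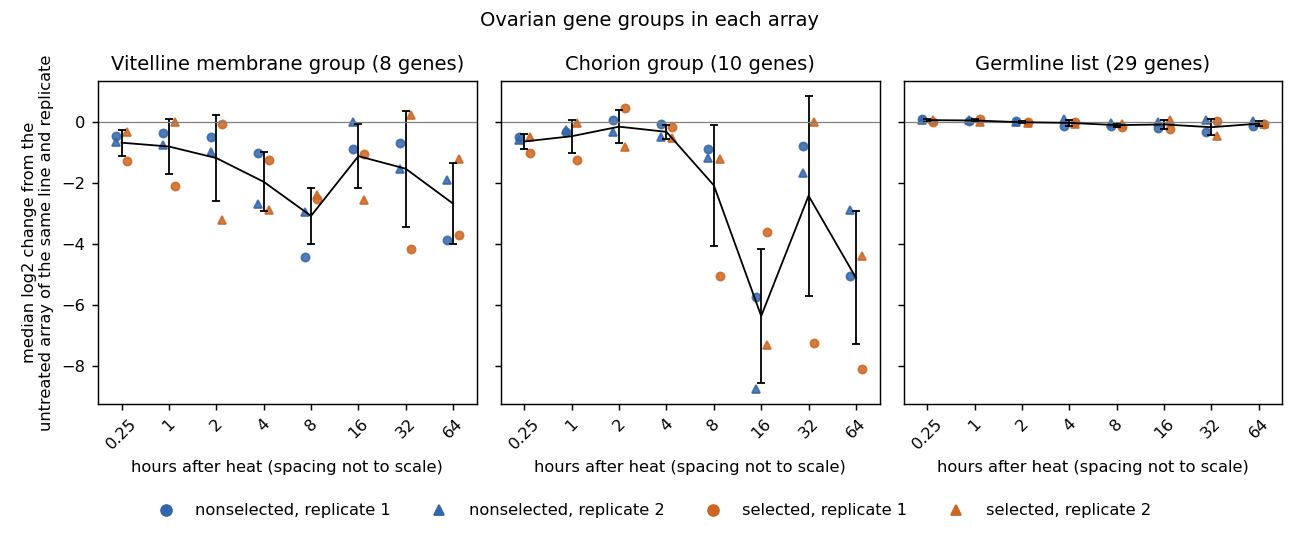
Median log2 change (y axis) of 8 vitelline membrane group genes, 10 chorion group genes and 29 germline genes in each array, against the untreated array of the same line and replicate, by hours after heat (x axis, not to scale). Symbols are circles for replicate 1 and triangles for replicate 2, blue nonselected and orange selected, and the black line gives the mean with the SD of 4 arrays. At 32 h selected replicate 1 stood at -7.23 for the chorion group, while the other arrays lay between -1.66 and -0.01.

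Other transcripts went up at 16 h. The phu signal rose from 3.15 ± 0.17, close to the background of the arrays, to 8.50 ± 0.98 log2 units (SD, n = 4, adjusted p = 5.79e-06). CG3739 rose at least 15.3-fold, Alp2 at least 13.0-fold, MtnA 6.85-fold, and Scp2, a sarcoplasmic calcium-binding protein gene, 5.56-fold. The trypsin family genes lambdaTry and zetaTry rose 2.43-fold and 2.42-fold and Ser6 1.81-fold, while Try29F was at least 3.72-fold lower, so 3 of 26 digestive protease genes rose and 1 fell. Among detoxification genes Cyp6a21 rose at least 2.26-fold and Cyp309a1 and Cyp12d1-d fell by 1.52 and 1.23 log2 units. Lsp2, a storage protein gene, fell by 2.41 log2 units (SE 0.43) and Obp99a by 1.56, 2 of 19 measured fat body and haemolymph genes. Listericin, an antibacterial peptide gene, was 4.04-fold higher at 8 h and 3.92-fold higher at 16 h, the 1 of 19 immune genes that passed at either time. The count of 196 at 16 h was lowest, 95, without selected 16 h replicate 1, and 8 of the 10 genes taken at this time kept their call whichever array was left out. Cp38 lost its call when any of 6 arrays was left out, and MtnA lost its call too.

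At 32 h 2 of the 8 measured clock genes rose and 1 fell (4 and 1 adjusted over the list alone), and no eggshell gene passed. The camera test of the clock list (adjusted p = 0.0171) was lost with an estimated correlation (adjusted p = 0.322). The tim transcript was 8.71-fold (adjusted p = 1.15e-05) and vri at least 3.39-fold higher than in untreated flies, and cry fell by 0.78 log2 units. Alp2 (at least 7.78-fold), MtnA (6.92-fold) and phu (to 6.48 ± 1.30 log2 units, SD, n = 4) rose. Ctr1B, a copper transporter gene, fell at least 3.56-fold (adjusted p = 0.00348). Fst (Frost), a gene known to be induced by cold, fell by 2.41 log2 units (SE 0.47), and Acbp6, an acyl-CoA-binding protein gene, by 2.92 (SE 0.66). Of 19 immune genes, pirk, a negative regulator of the immune deficiency pathway, rose at least 2.10-fold, and 5 rose adjusted over the list alone. None of the 22 yolk and eggshell genes passed, and the camera test of the list (adjusted p = 2.93e-05) was lost with an estimated correlation (adjusted p = 0.582). Cp19 stood at 10.73 ± 3.46 (SD, n = 4).

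At 32 h selected replicate 2 held transcripts of the male reproductive tract. Of 30 genes of the male reproductive list on the array, 23 had their highest value there, and the seminal fluid transcript Acp95EF stood at 9.69 log2 units against at most 2.31 in the other 35 arrays. Most of these probe sets lay under the filter, and the 1 measured member of the list did not pass at any time. Selected replicate 1 had low chorion transcripts (median log2 change -7.23). The count of 90 at 32 h became 490 without selected 32 h replicate 1, 21 without nonselected 32 h replicate 1, and 154 without nonselected 32 h replicate 2. Without selected 32 h replicate 2 it was 81. Of the 10 genes taken at this time 5 kept their call whichever array was left out, and MtnA, Fst and Acbp6 did not.

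At 64 h the largest number of probe sets differed from untreated flies. CG3739 was at least 13.9-fold, Alp2 at least 8.53-fold, MtnA 7.13-fold and Acsx3 at least 6.46-fold higher, and phu rose to 6.22 ± 1.61 log2 units (SD, n = 4; Acsx3 log2 change 2.74, SE 0.24, adjusted p = 4.38e-07). Chorion transcripts were low again, with Cp19 at least 161-fold, Cp18 at least 101-fold and Cp16 at least 70.1-fold lower, and Femcoat, another eggshell gene, at least 13.6-fold lower. In all, 10 of the 22 yolk and eggshell genes fell (19 adjusted over the list alone), Yp3 among them by 0.65 log2 units. The camera test of the list (adjusted p = 5.03e-20) was lost with an estimated correlation (adjusted p = 0.239). Of the 26 digestive protease genes, Try29F (at least 4.64-fold), Jon25Bi and epsilonTry fell, and lambdaTry, zetaTry, Ser12 and Ser6 rose, the last by 1.77-fold. Listericin rose 5.34-fold and pirk at least 2.03-fold, Lsp2 was at least 10.1-fold lower, and tim was 6.52-fold higher. The detoxification genes Cyp6a21 and Ugt35B1 rose, and Cyp309a1 and Cyp12d1-d fell. Obp19c, at least 19.0-fold lower, was the 1 odorant-binding gene of 12 that passed. The count of 293 fell to 123 without nonselected 64 h replicate 1, and 9 of the 10 genes taken at this time kept their call whichever array was left out.

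The calls at 16 h and 64 h overlapped, while those at 0.25 h and 64 h mostly did not. At 16 h and 64 h 86 probe sets were higher at both times and 64 lower at both, where independent lists would share 2.70 and 1.01. Unchanged groups simulated against the same untreated arrays shared 0. That value cannot show how much overlap the shared arrays add where many probe sets do change. With the untreated arrays split between the 2 times, the calls were fewer, 33 and 68 higher and 52 and 38 lower at 16 h and 64 h. Of these, 19 higher and 25 lower were shared. At 0.25 h and 64 h 1 probe set, without a symbol, was higher and 3, those of Kal1, CG7888 and Dip-B, were lower at both times (0.94 and 0.27 for independent lists, 0 in simulated unchanged groups, and 1 and 0 with split controls).

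In 5 other lists no single gene passed at any of the 8 times after heat, in the fit without a replicate block. These were 25 proteasome genes, 25 ribosomal protein genes, 26 cell cycle and replication genes, 21 flight and body muscle genes and 14 photoreceptor genes. Adjusted over the list alone, 6 photoreceptor genes rose at 32 h and 2 at 64 h, and 4 proteasome genes at 8 h, while the other 3 lists had none. The strongest camera call of each list, where it had any, is given here. The proteasome list had a median log2 change of 0.27 at 4 h (adjusted p = 1.21e-14, but adjusted p = 0.322 with an estimated correlation). The cell cycle list had a median of -0.34 at 32 h (adjusted p = 2.55e-05, and adjusted p = 0.582 with an estimated correlation). The ribosomal protein list had a median of 0.17 at 32 h (adjusted p = 1.25e-07, and adjusted p = 0.385 with an estimated correlation). The photoreceptor list had a median of 0.41 at 32 h (adjusted p = 0.00452, and adjusted p = 0.582 with an estimated correlation) and was also called at 64 h (adjusted p = 0.0163, and adjusted p = 0.648 with an estimated correlation). The muscle list had no camera call at these times. Of 28 constitutive chaperone genes, stv alone, which is also in the heat shock list, passed, from 0.25 to 8 h (2 genes at 4 h adjusted over the list alone). The strongest camera call of this list, at 1 h (adjusted p = 7.18e-05), was lost with an estimated correlation (adjusted p = 0.322). Of the Turandot stress genes 0 passed the filter.

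The next comparison asked whether the selected and the nonselected line differed in their heat response. No probe set passed the interaction F-test of limma (36 at an unadjusted p under 0.05) or the interaction at any single time (unadjusted counts from 11 at 1 h to 143 at 0.25 h). These counts lie below the share of 0.05 that unchanged probe sets would give, so the test was conservative here. The lack of calls therefore does not show equal responses. With the replicate block 0 passed as well. In untreated flies Hsp68 stood at 8.94 and 8.14 log2 units in the nonselected and 8.96 and 9.41 in the selected arrays (replicates 1 and 2). At 0.25 h it stood at 14.38 and 14.48 in the nonselected and 14.83 and 14.77 in the selected arrays. Levels after heat alone therefore do not compare the responses. The log2 changes of the lines, which share no arrays, correlated across probe sets with Pearson's r from 0.526 at 0.25 h to 0.852 at 16 h. Tested within a line, 2 arrays against 2, between 4 and 68 probe sets passed at a time in the nonselected line and between 4 and 51 in the selected line. Without selected 32 h replicate 1, 12 probe sets passed the interaction F-test, and without selected 64 h replicate 1, 10 did.

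The last comparison asked how the lines differed whatever the time. With the 36 arrays treated as independent, muscle and photoreceptor transcripts were higher and the storage protein transcript Lsp2 was lower in the selected line. No difference of this paragraph or the next passed with line and replicate number as a random block (0 probe sets), and Lsp2 alone passed with means of 2 against 2. Over all 9 times, 1000 probe sets differed (503 higher and 497 lower in the selected line), 650 of them with the same sign at all 9 times. Of 21 flight and body muscle genes 17 were higher and none lower (20 adjusted over the list alone), with Msp300, a large muscle scaffold protein, at 2.02-fold (log2 difference 1.01, SE 0.18, adjusted p = 0.00146), TpnC41C, a troponin C, at 1.96-fold and Mlc1, a myosin light chain, at 1.93-fold. Of 14 photoreceptor genes 7 were higher (11 adjusted over the list alone), among them the light channel gene trpl at least 1.72-fold and the arrestin genes Arr1 and Arr2 at 1.56-fold and 1.53-fold. The camera tests of these lists (adjusted p = 2.42e-19 and 1.32e-08) were lost with an estimated correlation (adjusted p = 0.273 for each). Also higher were Ms (myosuppressin) at least 2.01-fold and RIC-3, a chaperone of acetylcholine receptors, 2.02-fold. Sgp (2.27-fold), the cuticle gene Cpr49Ae (at least 2.16-fold) and Lectin-galC1 (at least 2.10-fold) were also among the highest.

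With the arrays treated as independent, storage, protease and yolk transcripts were among those lower in the selected line, and of these Lsp2 alone passed with means of 2 against 2 and none with the random block. Lsp2 was at least 6.65-fold lower (log2 difference -2.85, SE 0.20, adjusted p = 2.27e-08). The gut protease genes Jon25Bii, Jon99Ci and Jon25Bi were 2.55-fold, 1.85-fold and 1.77-fold lower, fit, a fat body gene, 1.98-fold, Tsf1, an iron transport protein gene, 1.73-fold, and Mur2B at least 1.51-fold, which lost its call when 1 of several arrays was left out. The yolk protein genes Yp1, Yp2 and Yp3 were lower by 1.24-fold, 1.40-fold and 1.35-fold, 3 of 22 yolk and eggshell genes (7 adjusted over the list alone). None of the 7 heat shock genes differed, and stv had the largest difference (1.42-fold higher, adjusted p = 0.0815). In other lists, detoxification had 5 genes higher and 3 lower of 39, the clock list 1 higher of 8 (vri, at least 1.34-fold), cell cycle and replication 4 lower of 26 (CycB, 1.19-fold), the immune list 1 lower of 19 (PGRP-SB1, at least 2.04-fold), glycolysis 2 higher of 15, antioxidant defence 1 higher of 19 (Cat, 1.26-fold), odorant-binding 3 higher of 12, and digestive proteases 1 higher and 3 lower of 26. The proteasome list had 1 gene lower of 25 (Prosbeta3, 1.14-fold), constitutive chaperones 1 higher of 28 (l(2)efl, 1.44-fold), fat body and haemolymph proteins 3 higher and 2 lower of 19, and ribosomal proteins none of 25.

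The line difference rested on treating the 9 arrays of a line and replicate number as independent, and replicates of a line differed in the same way at most times. When each line and replicate number was treated as 1 correlated unit (limma's duplicateCorrelation, consensus correlation 0.392), 0 probe sets passed (325 at an unadjusted p under 0.05), and with their means, 2 against 2, 1 passed (Lsp2). The mean of the muscle list, relative to the mean of all 4, was 0.06 and -0.86 in nonselected replicates 1 and 2, and 0.16 and 0.64 in selected replicates 1 and 2. Fitted within each replicate number, 582 probe sets passed in replicate 1 and 2975 in replicate 2, 235 of them in both with the same sign, and the line differences correlated across probe sets with r = 0.223. Over all tested probe sets, both selected means lay beyond both nonselected means in 27.0%, where 33.3% would if all orders of the 4 means were equally likely. They were not, since replicate 1 against replicate 2 gave 4178 calls. The 2 shares therefore do not measure the line difference. The count became 1564 without selected 32 h replicate 1.

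**Figure D4:**
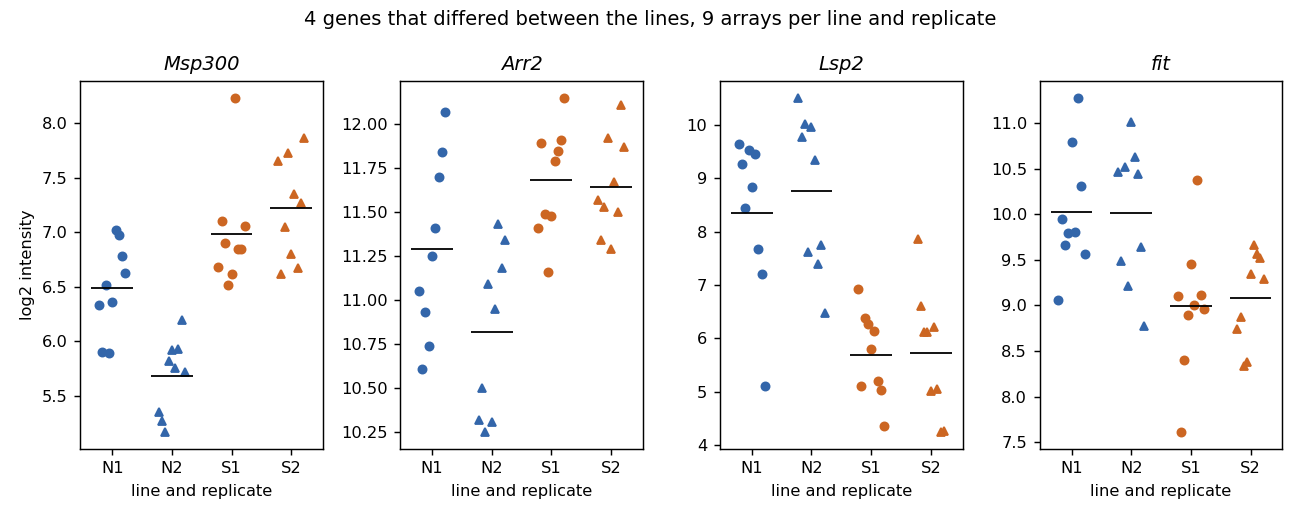
Log2 intensity (y axis) of 4 genes in each array, grouped by line and replicate (x axis: N1 and N2 are nonselected, S1 and S2 selected replicates 1 and 2), with 9 arrays each over all times and a black bar at the mean. Msp300 had means of 6.49 and 5.68 in N1 and N2 against 6.98 and 7.22 in S1 and S2, and Lsp2 had means of 8.35 and 8.76 against 5.69 and 5.72.

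In untreated flies no probe set passed as different between the lines (148 at an unadjusted p under 0.05, 2 arrays against 2 in limma). That count lies below the share of 0.05 that unchanged probe sets would give, so the test was conservative. The lack of calls does not show that untreated lines were alike. Untreated Lsp2, for example, stood at 9.64 and 10.51 log2 units in the nonselected and 6.92 and 7.86 in the selected arrays. Of the single times after heat, 0.25 h gave 7, Lsp2 and the lysozyme gene LysS among them, 4 h gave 1 (Lsp2) and the others 0 (unadjusted counts from 57 at 16 h to 824 at 32 h).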

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

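The search for male transcripts in single arrays was chosen after the results were seen, and the test of degraded RNA was planned before. For each gene list and time, the 4 arrays (2 lines, 2 replicates) were searched for 1 array far from the other 3 in mean log2 level (Dixon's test at its 95% critical value). Chance picks about 1 in 20 groups. Of 144 groups, 7 were picked, where 7.20 would be by chance.

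The heat shock list at 4 h stood at 11.63 in nonselected replicate 2 (nearest other array 11.76). Glycolysis genes stood at 10.55 at 2 h in selected replicate 2 (nearest 10.25), at 10.15 at 16 h in nonselected replicate 2 (nearest 10.34) and at 10.20 at 64 h in nonselected replicate 2 (nearest 10.42). Ribosomal protein genes stood at 13.05 at 2 h in nonselected replicate 1 (nearest 13.08). Fat body and haemolymph genes stood at 9.29 in untreated nonselected replicate 1 (nearest 9.08) and at 9.28 at 4 h in nonselected replicate 1 (nearest 8.94).

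The male reproductive list at 32 h was looked at because it had been seen to stand out, and is not among these groups. It stood at 6.34 in selected 32 h replicate 2, where the nearest of the other 3 arrays had 3.58. Of its 30 genes, 23 (76.7%) had their highest value of all arrays there, 17 of them by more than 2 log2 units, while no other array held the highest value of more than 5. The transcript EbpII of the ejaculatory bulb stood at 10.72 there against at most 2.53 elsewhere, the seminal fluid transcripts Acp95EF at 9.69 against 2.31 and SP at 6.23 against 1.30, and the testis transcript Mst84Da at 8.69 against 2.48. RNA from male flies fits these values. The 3' to 5' ratio gave no sign of degraded RNA. This array ranked 30 of 36, but all replicate 2 arrays had lower ratios than all replicate 1 arrays. Among replicate 2 arrays, whose log2 ratios ran from 1.26 to 1.79, this array stood at 1.51. How male RNA came into the sample was not tested, and no biological explanation was tested.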

How the results depend on the processing

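The fits without the probe sets that stood out in selected 32 h replicate 2 were chosen after the results were seen, and the other alternatives were planned. Signal near the background of the arrays limits what can be compared, since changes of transcripts under an intensity of 32 were not tested. Where a value differs from that of the report, the cause was not tested unless stated.

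Counts kept within 1.5 times the reported count under trend and robust moderation, added quantile normalization, median centring and a pseudocount. The stricter filter gave 51 at 32 h and 647 for the line difference, and no filter gave 1 probe set for untreated flies. The adjusted p threshold of 0.01 gave, from 0.25 to 64 h, 37, 51, 53, 13, 38, 101, 23 and 117, 644 over the series and 307 for the line difference, which follows from a stricter threshold. A log2 change of at least 1 gave 34, 47, 49 and 18 from 0.25 to 4 h, 52 at 32 h, 169 at 64 h, 343 over the series and 20 for the line difference. Fits of only the arrays compared gave 14 at 4 h, 199 at 8 h, 122 at 16 h and 10 at 32 h. With the line and replicate number as a random block 0 probe sets differed between the lines, and with means of 2 against 2, 1. Of 64 list calls by camera, which tests a list against other genes, 4 held with an estimated correlation. Of the same calls 14 passed with fry, which asks whether a list changed at all, a different question.

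Replicate numbers did not pair the arrays by the rule that every pair correlate above 0.1. Differences between replicates correlated between times from 0.329 to 0.782 in the nonselected line, from -0.347 to 0.606 in the selected line (30 of 36 pairs of times above 0.1), and from -0.434 to 0.683 across lines (55 of 81). With the replicate block, counts were 121, 224, 180, 63, 185, 399, 257 and 615 from 0.25 to 64 h, 2064 over the series and 2349 for the line difference. With the block within line they were 147, 326, 228, 104, 292, 533, 465, 832 and 2633.

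With the arrays of 64 h as reference, counts were 820, 965, 675, 328, 4 and 22 at 0.25, 1, 2, 4, 16 and 32 h. Since that reference itself differs from untreated flies, log2 changes turned sign for tim (-0.54) and CG18180 (0.41) at 4 h, Alp2 (-0.32), phu (-0.30) and CG14834 (0.80) at 8 h, MtnA (-0.059), Cp19 (0.11), Cp18 (0.051) and Cp16 (0.32) at 16 h, and Alp2 (-0.13), MtnA (-0.044), CG7214 (0.057), Acbp6 (0.15) and CG16956 (0.625) at 32 h. Over all settings other than left-out arrays, named genes kept their call in 947 cases, lost it in 129 and turned sign in 14. With arrays left out, they kept it in 1166 and lost it in 194.

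With each array left out in turn, a lone array being assumed to vary like other groups, counts ran from 39 to 50 at 0.25 h, 47 to 82 at 1 h, 53 to 79 at 2 h, 12 to 23 at 4 h, 36 to 66 at 8 h, 95 to 227 at 16 h, 21 to 490 at 32 h and 123 to 339 at 64 h. They ran from 930 to 1501 over the series, 670 to 1564 for the line difference, 0 to 0 for it in untreated flies, 0 to 12 for the interaction F-test, and 0 to 18 summed over the interactions at single times. Untreated arrays moved counts beyond 1.5 times as follows: nonselected replicate 1 at 0.25 h (41), 1 h (64), 4 h (17) and 32 h (40), selected replicate 1 at 0.25 h (39), 1 h (47), 2 h (53), 8 h (49), 16 h (119), 32 h (32) and 64 h (151), nonselected replicate 2 at 1 h (67), 2 h (61), 4 h (19), 8 h (47), 16 h (116), 32 h (32) and 64 h (159), and selected replicate 2 at 1 h (69), 4 h (16), 8 h (46), 16 h (125), 32 h (34) and 64 h (178). Arrays of the time itself did so for nonselected replicate 1 at 2 h (54), 8 h (41), 16 h (101), 32 h (21) and 64 h (123), selected replicate 1 at 1 h (61), 8 h (36), 16 h (95), 32 h (490) and 64 h (144), nonselected replicate 2 at 4 h (19) and 32 h (154), and selected replicate 2 at 4 h (12). Selected 32 h replicate 1 moved the line difference (1564), and for the interaction F-test it gave 12, selected 64 h replicate 1 gave 10, selected 8 h replicate 2 gave 2, and both nonselected 16 h replicates gave 1 each. Summed single times gave 18, 12, 2, 1 and 1 without the same arrays, and 1 each without selected 0.25 h replicate 1 and nonselected 4 h replicate 2. Leaving out the 8 tested probe sets that stood more than 2 log2 units above all other arrays in selected 32 h replicate 2, too few to move much, gave 1087 over the series, 90 at 32 h and 1006 for the line difference. Leaving out that array gave 1056, 81 and 832.

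Other splits of the 8 arrays of a time and its untreated flies, 35 in all with the real one, were fitted alone without covariates. At 0.25, 1, 2, 4, 8 and 16 h 2 splits gave as many calls as the real one, itself included, so the count of splits alone did not exclude chance. The real split gave 34, 67, 69, 16, 180 and 147 and the highest other 51, 340, 319, 950, 190 and 714. From 1 to 16 h the only other split as large was replicate 1 against replicate 2, which points to a structure of the samples that the replicate number marks. Fitted within each replicate number, 20, 26, 27, 8, 23 and 58 probe sets passed in both with the same sign at 0.25, 1, 2, 4, 8 and 16 h, and log2 changes over all tested probe sets correlated by 0.643, 0.687, 0.414, 0.507, 0.752 and 0.739. At 0.25 h the other split as large was mixed, and the replicate split gave 22. At 32 h and 64 h 1 split, the real one, gave as many (10 and 183, highest other 0). With 35 splits for each of 8 times, a first rank at some time does not by itself exclude chance. For the line difference 1 of 100 splits within times did (1481, highest other 816), though replicate 1 against replicate 2 gave 4178. The random splits break up the sets of arrays of a line and replicate number. They therefore cannot tell a line difference from a difference between such sets. The remaining pairing of whole sets gave 390. For change over time 1 of 100 did (1615, highest other 74).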

Other observations

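The tests of time of day and of a gap in eggshell genes, the use of the random block to explain the line difference and the arrays that stand apart were chosen after the results were seen, while the random block itself and the tests of time of day in late genes and of ovaries were planned before. In selected 64 h replicate 2, 30 probe sets stood more than 2 log2 units above all other arrays, among them neo (7.19 against at most 3.20), the mucin gene Muc26B (6.51 against 3.17) and Osi15 (8.39 against 5.49). In selected 8 h replicate 1, 6 did, with the adult cuticle gene Acp1 (12.39 against 7.03), the cuticle protein genes Cpr92F (7.19 against 3.70) and Cpr62Bc (4.41 against 1.97), Acp65Aa (6.70 against 4.02) and Vajk3 (7.26 against 4.25).

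Eggshell genes were low at 16 h and 64 h, and 3 explanations were weighed. Fewer ovaries in the pooled flies are excluded as the cause, since germline transcripts had a median log2 change of -0.103 at 16 h, with a lowest value of -0.42 over 29 genes. A gap in egg chambers that passes through the stages, thought of after the values were seen, predicts vitelline membrane genes low first and chorion genes later, and the change from 8 h to 16 h was 6.05 log2 units more negative in chorion genes (-6.05). It stays open, since 1 of the 4 line and replicate sets had only -0.54 (others -7.98, -9.30 and -6.38), egg chambers were not counted, and 1 passing gap does not predict both groups low at 64 h (medians -2.82 and -4.88) after 32 h (-1.51 and -2.65). Time of day cannot be told apart from it, since 32 h minus 8 h was 1.083 in the median (sets from -1.47 to 2.76; vitelline membrane genes 1.72, chorion genes -0.46) and 64 h minus 16 h was -0.06 (sets from -3.42 to 2.78; -1.46 and 0.82), so that sets and gene groups went both ways.

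Genes that differed at 8 h or later could follow the time of day, since 16 h and 64 h, and 8 h and 32 h, lie whole days apart. With separate arrays and controls, 16 h correlated with 64 h by 0.129 more than with 32 h (11 of 12 comparisons positive), but 8 h correlated with 32 h by 0.124 less than with 16 h (-0.124, 0 of 12 positive). The 12 comparisons reuse the same few line and replicate sets and are not independent. They also include both selected 32 h arrays, which stood apart in male or chorion transcripts. Time of day cannot be told apart from other explanations here. Nor can heat be told apart from the age of the flies, since no untreated flies were sampled at these times. The clock genes tim and vri were among those that rose. For the line difference, 0 probe sets passed when arrays of a line and replicate number were modelled as correlated, and differences between replicates correlated above 0.1 in 36 of 36 pairs of times in the nonselected and 30 of 36 in the selected line.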
